A study of Juglans regia with 12 samples.

How the data were processed

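Flower buds of Persian walnut (Juglans regia) of an early-flowering, precocious type and of a late-flowering type were profiled in 12 libraries, 3 mRNA and 3 small RNA libraries of each type. Groups and replicate numbers were taken from the sample titles. The labels do not say that the replicates came from separate trees, so p-values measure only the spread between these samples, which may be technical. The library protocol names 16 libraries, of which 12 were analysed here. That protocol describes a stranded poly(A) mRNA kit for every sample, and how the small RNA libraries were built is not given in the sources used here.

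The deposited mRNA table holds a read count and an FPKM value per gene and library, per the file headers. The FPKM values equal the read count divided by the gene length in kilobases and by the library's summed counts, scaled as the unit requires. The largest relative difference was 3.8e-08. Per the submitters' processing notes, FastQC, HISAT2, Cufflinks and DESeq2 were used, without a stated role. The genome build and the annotation are not given in the sources used here. The table lists 31425 gene IDs with lengths of 87 to 19541 bases (median 1186), of which 67.9% are multiples of 3. None of these IDs matched the reference gene table (0 of 31425 IDs, against 37996 reference genes), so genes carry no names, and the planned tests of gene lists (0 tested) and of predicted miRNA targets were not made.

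The deposited miRNA table holds a raw count per mature sequence and library, with the name of a matching miRNA of another species and a family column. The mapping and naming tools for these counts are not given in the sources used here. It lists 931 sequences of 18 to 25 bases. Of these, 239 have no family in that column and hold 0.579% of the counts, and 26 have a family that differs from the matched name. Families were therefore taken from the number in the matched name, with miR156 and miR157 joined. Sequences of 21 bases hold 85.4% of the counts. The column totals cover reads matched to listed miRNAs only and are not the depth of the small RNA libraries.

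Counts were tested with edgeR 4.0.16 in R 4.3.3, using TMM scaling, filterByExpr on the groups with a minimum count of 10, and robust quasi-likelihood fits with the walnut type as the only term. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05, and fold changes are early-flowering minus late-flowering on the log2 scale. Levels are CPM of the TMM-scaled library, given as mean ± SD. The filter left 21740 genes and 243 miRNA sequences for testing, and 9685 genes and 688 sequences were not tested. Intervals are at the 95% level. A floor of 3 counts corresponds to 0.128 to 0.178 CPM in the mRNA libraries and to 4.64 to 9.69 CPM in the miRNA libraries, and it covers counting error only.

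The tests, samples, alternatives, miRNA lists and the rule for naming features were fixed before the data were examined. For mRNA without names, the rule took the 2 highest and 2 lowest fold changes among genes past the threshold with an absolute log2 fold change of at least 1, no overlap between groups and a mean of at least 5 CPM in the higher group, which 1736 genes met. For miRNA it took the 6 highest and 6 lowest fold changes past the threshold under the same limits on overlap and level, plus the most abundant tested sequence of each listed family. Summing sequences per family, which adds sequences matched to 5p and to 3p arms, was chosen after seeing the data. Family sums were first scaled with their own TMM factors, which gave 7 calls, and then with the sequence-level factors, which gave 5 and are reported; the family scaling was thus set with both counts known. Of 37 families tested, those outside the fixed lists are named as chosen after their values were seen.

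Alternatives covered DESeq2 size factors, quantile normalization, DESeq2 1.42.0, limma-trend (limma 3.58.1), no filter, a filter of at least 10 CPM in 3 libraries, other thresholds, a replicate block and each library left out in turn. Alternatives added after seeing the data were the family sums with their own scalings, the merging of near-identical sequences, scaling by total counts and TMM without the most abundant sequence. Merging joined a sequence to one at least 10 times more abundant that differed by 1 substitution or by up to 3 end bases, and it joined 230 sequences. The fits were tested on simulated counts. For mRNA genes (21740), with changes planted in 200, 58.2% of those of log2 1 and 90% of log2 2 were recovered, with 6.37% false calls. For miRNA sequences (243), with 30 planted, the shares were 6.67% and 57.1%. For families (37), scaled with their own TMM factors and with 8 planted, they were 50% and 100%, from 4 families of each size. Each was 1 simulated draw. Recovery depends on the share of features changed, so the mRNA rates do not carry over to the larger share called in these data. Replicate libraries were compared by chi-square per degree of freedom, which lay between 8.88 and 29.3 for mRNA and between 32.8 and 150 for miRNA, so no library was counted as a duplicate.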

Results

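Levels of mRNA and miRNA were compared between flower buds of an early-flowering walnut type, which bears precociously, and those of a late-flowering type, with 3 libraries of each type per assay. The mRNA libraries held 19053541, 16897407 and 16980496 gene counts in the early-flowering type and 18284067, 23429891 and 19567426 in the late-flowering type. The miRNA libraries held 309697, 611620 and 646408 counts in the early-flowering type and 614838, 447102 and 473151 in the late-flowering type. The labels give an early flower stage to the first type and a late flower stage to the second, so type and any difference of bud stage cannot be separated.

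The first question was which miRNAs differed between the bud types. miR156/miR157, the regulator of SPL genes that marks the juvenile phase, was lower in early-flowering buds, at 12719 ± 1600 CPM against 35886 ± 5229 CPM (SD, n = 3 each; log2 fold change −1.50, SE 0.24, edgeR adjusted p = 0.00210). miR172, which targets AP2-like repressors of flowering, was higher, at 6733 ± 422 CPM against 2971 ± 387 CPM (log2 1.18, SE 0.18, edgeR adjusted p = 0.00201). miR319, a regulator of TCP genes, was also higher, at 7355 ± 1013 CPM against 3258 ± 553 CPM (log2 1.17, SE 0.20, edgeR adjusted p = 0.00276). miR2950 showed the highest fold change of the 5 families that passed, at 669 ± 78.6 CPM against 171 ± 18.5 CPM (log2 1.96, SE 0.28, edgeR adjusted p = 0.00201); it lies outside the lists and was named after its values were seen. miR827, known from phosphate homeostasis, was lower, at 10967 ± 863 CPM against 20280 ± 1529 CPM (log2 −0.89, SE 0.21, edgeR adjusted p = 0.0175).

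Of the 37 families tested, 3 rose and 2 fell in early-flowering buds. Both miR159, with a log2 fold change of 0.53, and miR167, with −0.62, had an edgeR adjusted p of 0.0829, and both passed under 4 other scalings, which gave 7 calls each. miR827 lost its call without early-flowering replicate 3, without late-flowering replicate 2 and with the replicate block, where its edgeR adjusted p reached 0.109. Without early-flowering replicate 1, the miRNA library with the lowest total of listed miRNAs, 19 families passed, 10 higher and 9 lower.

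**Figure D1:**
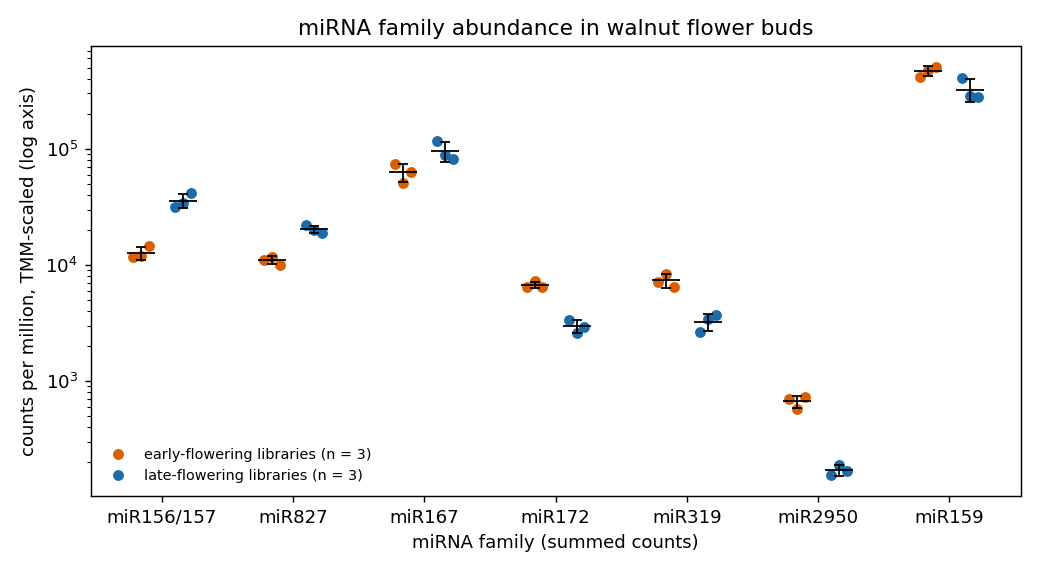
Abundance of 7 miRNA families in each library, as TMM-scaled CPM on a log axis, with points for libraries and bars for the mean and SD of 3 libraries per type. miR156/miR157 averaged 12719 in early-flowering and 35886 in late-flowering buds and miR172 averaged 6733 and 2971, while miR159 and miR167 did not pass the test with the scaling drawn.

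The ratio of miR172 to miR156/miR157 counts inside a library, which no scaling alters, was 0.556, 0.607 and 0.445 in early-flowering buds and 0.106, 0.0760 and 0.0704 in late-flowering buds. The mean log2 ratio was −0.91 ± 0.23 against −3.59 ± 0.32 (SD, n = 3 each), a 6.41-fold difference. The exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries allow.

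Among single sequences, 28 of 243 changed, 12 higher and 16 lower in early-flowering buds. In the phase change and flowering list (miR156, miR157 and miR172), 3 of 35 tested sequences rose and 11 fell, or 3 and 17 when adjusted over the list alone. All 11 that fell belong to miR156/miR157, whose 27 tested sequences had negative fold changes under TMM, DESeq2 size factors, total counts and quantile normalization. These 11 were 11 of the 16 lower sequences (Fisher's exact test on sequences, which are not independent, p = 1.2e-08). The most abundant, jre-MIR156-5 (TTGACAGAAGATAGAGAGCAC), averaged 4669 ± 828 CPM against 16577 ± 4601 CPM (n = 3 each; log2 −1.83, SE 0.27, edgeR adjusted p = 0.00536). The opposite-arm sequence jre-MIR156-30 averaged 1125 ± 119 CPM against 4489 ± 785 CPM (log2 −2.00, edgeR adjusted p = 0.00536), and jre-MIR156-25, also matched to a 3p arm, had the lowest fold change, at 6.49 ± 4.08 CPM against 82.5 ± 27 CPM (log2 −3.52). The remaining lowest sequences were jre-MIR156-50 (log2 −2.07), jre-MIR156-36 (−1.99) and jre-MIR159-38 (−1.88), the last matched to miR156 by name. Both jre-MIR156-50 and jre-MIR159-38 merge into jre-MIR156-5. Early-flowering counts were near the floor of 3 for jre-MIR156-25 (1, 3 and 7), jre-MIR156-50 (4, 2 and 10) and jre-MIR159-38 (3, 9 and 13). After near-identical sequences were merged, 8 of 13 miR156/miR157 sequences and 1 of 6 miR172 sequences passed, the latter jre-MIR172-2.

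jre-MIR172-2 (AGAATCTTGATGATGCTGCAT), the most abundant miR172 sequence, averaged 5177 ± 515 CPM against 1979 ± 119 CPM (n = 3 each; log2 1.39, SE 0.20, edgeR adjusted p = 0.00536), and jre-MIR172-22 averaged 319 ± 72.9 CPM against 83.6 ± 18.7 CPM (log2 1.92). In the GAMYB and TCP list (miR159 and miR319), 5 of 27 sequences rose and 0 fell, or 8 and 0 when adjusted over the list alone. After near-identical sequences were merged, 1 of 14 rose, jre-MIR159-3. The 5 include jre-MIR159-32, matched to miR319 (log2 2.43, edgeR adjusted p = 0.0272). Its late-flowering counts of 3, 11 and 10 were near the floor of 3, and it merges into jre-MIR319-1. That parent did not pass before merging (edgeR adjusted p = 0.0624) or after it (edgeR adjusted p = 0.132). Another of the 5 is jre-MIR159-14 (log2 1.76, 501 ± 62.0 CPM against 148 ± 4.63 CPM). jre-MIR159-14 is matched to miR159 but merges with jre-MIR159-3, a miR319 sequence, so the names of these families overlap. jre-MIR159-3 averaged 5103 ± 364 CPM against 2398 ± 260 CPM (log2 1.09, edgeR adjusted p = 0.0143). The most abundant sequence of all, jre-MIR159-2, held 26.3% to 44.4% of each library and did not pass (log2 0.49, edgeR adjusted p = 0.155).

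Outside these lists, jre-MIR2950-1 averaged 597 ± 87.7 CPM in early-flowering buds and was 3.80 times as abundant as in late-flowering buds (n = 3 each; log2 1.93, SE 0.26, edgeR adjusted p = 0.00536). jre-undef-186, the first 18 bases of jre-MIR2950-1, had a log2 fold change of 2.29, with late-flowering counts near the floor (5, 4 and 11). In the meristem and organ polarity list, 2 of 62 sequences rose and 1 fell, or 1 and 1 adjusted over the list alone. Of these, jre-MIR171_2-2, of the family that targets HAM-type GRAS genes, averaged 252 ± 52.2 CPM against 81.3 ± 17.4 CPM (log2 1.63, edgeR adjusted p = 0.0140). The summed miR171 family did not pass (log2 0.64, edgeR adjusted p = 0.229). Its most abundant sequence, jre-MIR171_2-10, did not pass either (log2 0.81, edgeR adjusted p = 0.174). That sequence, matched to a 5p arm and unlike jre-MIR171_2-2, averaged 10205 of the family's 13725 CPM in early-flowering buds. In late-flowering buds it averaged 5806 of 8784 CPM. The sum thus reflects mostly jre-MIR171_2-10 and says little on jre-MIR171_2-2. Of 11 tested miR171 sequences, 8 had positive and 3 negative fold changes. In the auxin signalling list 0 of 30 rose and 1 fell, or 0 and 0 adjusted over the list alone, and the most abundant miR167 sequence, jre-MIR167_2-3, had a log2 fold change of −0.86 (edgeR adjusted p = 0.0591) that passed in 9 of 16 alternatives. In the nutrient and copper list 0 of 41 rose and 2 fell, or 0 and 0 adjusted over the list alone; both were miR827, led by jre-MIR827_4-4 (8669 ± 635 CPM against 16536 ± 1768 CPM, log2 −0.93, edgeR adjusted p = 0.0199). In the NBS-LRR and MYB phasiRNA trigger list 0 of 14 rose and 1 fell, or 0 and 1 adjusted over the list alone. None of the 14 sequences in the miRNA pathway feedback list passed (0 also adjusted over the list alone), and 0 miR535 sequences were tested. Of the most abundant sequences of 24 listed families, 4 passed and 20 did not, with log2 fold changes of −0.86 to 1.43 among the latter. The highest, jre-MIR395-9, was at 0.55 without early-flowering replicate 2, and without early-flowering replicate 1 it was at 1.77 and passed (edgeR adjusted p = 0.00935). After merging, 1 sequence of the nutrient and copper list and 2 of the auxin list were lower. The 1 call of the NBS-LRR and MYB list, jre-MIR482-22, merged into jre-MIR482-23, which was lower only after merging.

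Of the named sequences, jre-MIR156-30 and jre-MIR156-25 passed in 16 of 16 alternatives. Without early-flowering replicate 3, the log2 value was −4.30 for jre-MIR156-25 and −2.81 for jre-MIR156-50. The call was lost in 1 of 16 for jre-MIR156-5 and jre-MIR2950-1, in 1 of 15 for jre-MIR172-22 and jre-MIR159-14, in 3 of 16 for jre-MIR172-2, jre-MIR171_2-2 and jre-MIR156-36, and in 3 of 15 for jre-MIR159-38. It was lost in 4 of 15 for jre-MIR159-32, in 5 of 15 for jre-MIR156-50, in 5 of 16 for jre-MIR827_4-4 and jre-undef-186, and in 6 of 16 for jre-MIR159-3. The count of changed sequences varied with the library left out. It was 54 without early-flowering replicate 1 and 17 without late-flowering replicate 1. It was 7 without early-flowering replicate 2 or late-flowering replicate 2, and 2 without late-flowering replicate 3. Without late-flowering replicate 3, jre-MIR156-5, jre-MIR2950-1, jre-MIR172-22 and jre-MIR159-14 each missed the threshold at an edgeR adjusted p of 0.0555. Over the left-out libraries their log2 values were −2.019 to −1.708, 1.674 to 2.002, 1.697 to 2.107 and 1.613 to 1.785, in that order. For these sequences the call depended on the library left out more than the fold change did. At an unadjusted p under 0.05, 83 sequences passed, and quantile normalization moved the median log2 fold change of all tested sequences from 0.13 to 0.02.

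**Figure D2:**
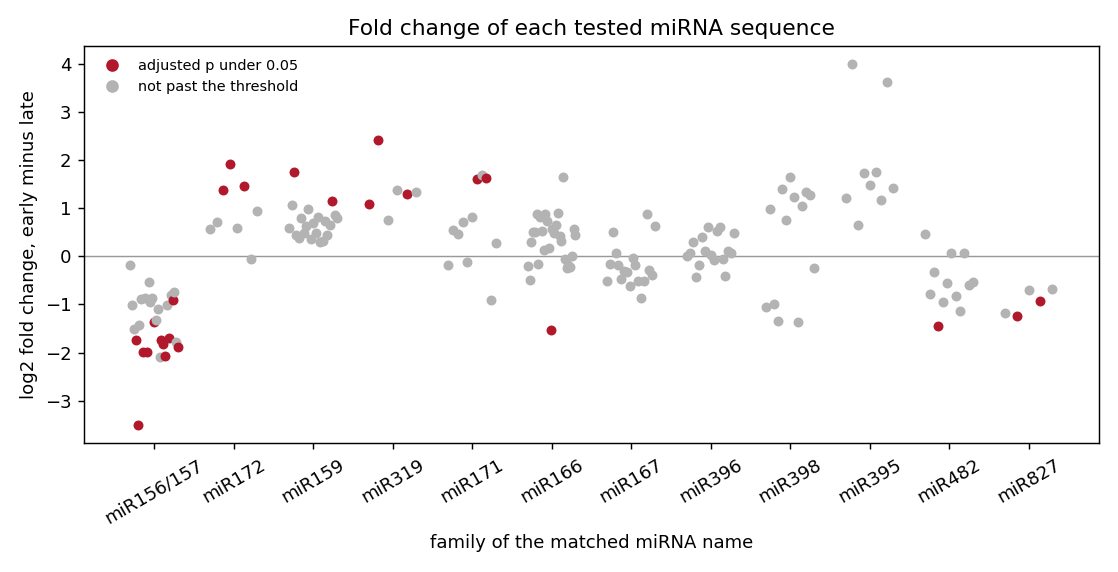
Log2 fold change (early minus late) of each tested miRNA sequence in 12 families, with points past the adjusted p threshold of 0.05 in red and others in grey. The 27 miR156/miR157 sequences lie below 0, with 11 past the threshold, and 3 of the 8 miR172 sequences rose; merging near-identical sequences left 8 and 1.

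The second question was how mRNA levels differed between the same bud types. Of 21740 genes tested, 5901 (27.1%) changed, 3077 higher and 2824 lower in early-flowering buds (edgeR, 3 libraries per type). Genes that rose had a median log2 fold change of 0.99 and a median level of 13.6 CPM, and genes that fell had −0.67 and 32.8 CPM. An absolute log2 fold change of at least 1 was met by 1524 of the genes that rose and 833 of those that fell, and one of at least 2 by 177 and 218. The gene table does not pair its IDs with names, so gene functions are not described.

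The highest fold changes under the naming rule were those of Jr7SG00059500, at 8.91 ± 5.93 CPM against 0.540 ± 0.194 CPM (n = 3 each; log2 4.06, SE 0.58, edgeR adjusted p = 0.00712), and Jr3DG00220700, at 13.3 ± 5.60 CPM against 0.959 ± 1.49 CPM (log2 3.86, SE 1.02, edgeR adjusted p = 0.0340). The log2 value of the first was 3.38 without early-flowering replicate 1. That of the second was 7.01 without late-flowering replicate 1 and 3.24 without late-flowering replicate 2, and its call was lost in 6 of 12 alternatives. The lowest were those of Jr3DG00208500, at 0.965 ± 0.434 CPM against 79.7 ± 83.3 CPM (log2 −6.34, SE 0.999, edgeR adjusted p = 0.00916), and Jr2DG00235700, at 2.04 ± 1.23 CPM against 98.1 ± 63.1 CPM (log2 −5.56, SE 0.62, edgeR adjusted p = 0.00494). Both kept their call in 13 of 13 alternatives, but single libraries moved their size. The log2 value of Jr3DG00208500 was −5.03 without late-flowering replicate 2, and that of Jr2DG00235700 was −6.15 without early-flowering replicate 1 and −4.89 without late-flowering replicate 3. In FPKM, Jr3DG00208500 averaged 0.859 ± 0.390 against 66.2 ± 69.2. No gene had 0 counts in each library of one type and at least 20 in each of the other (0 genes in either direction).

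Direction varied with abundance. When genes were divided into 5 equal bins by mean CPM, in the lowest bin 687 rose and 216 fell, with a median log2 fold change of 0.31, and in the highest bin 368 rose and 854 fell, with a median of −0.07. The median over all genes was −0.01. Correlations of log2 CPM across genes were 0.964 to 0.984 within a type and 0.893 to 0.968 between types. The first principal component held 70.2% of the variance and separated the types, with scores of 33.9 to 64.1 for early-flowering and −83.9 to −20.3 for late-flowering libraries. The count of changed genes fell to 1317 without early-flowering replicate 2, 2156 without early-flowering replicate 3, 2702 without late-flowering replicate 2 and 3606 without late-flowering replicate 3.

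**Figure D3:**
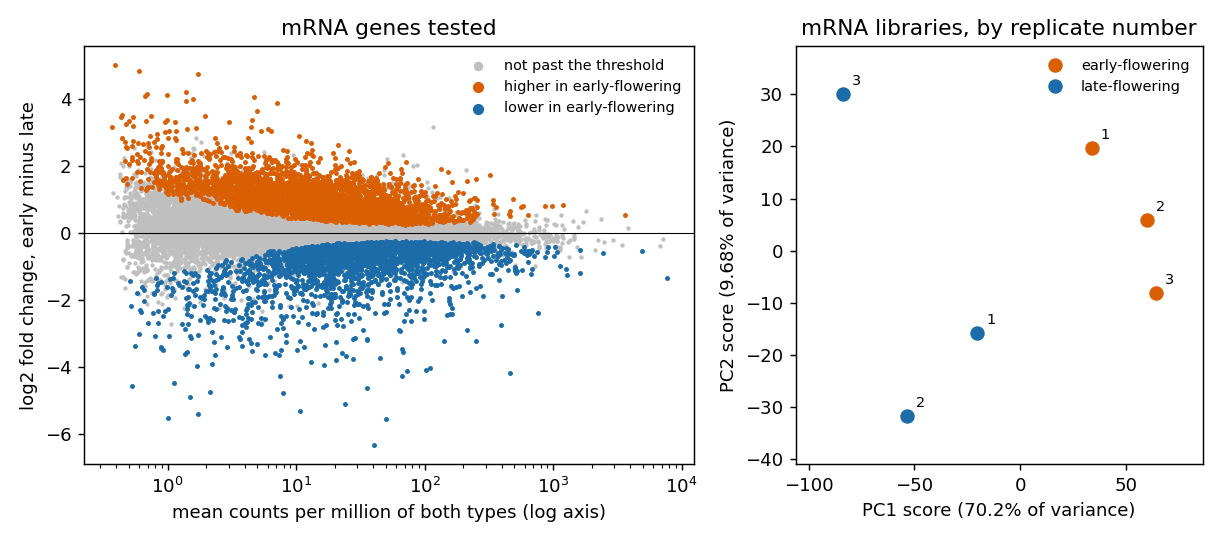
Left, log2 fold change (early minus late) of each tested gene against its mean CPM on a log axis, with the 3077 higher genes in orange and the 2824 lower genes in blue. Right, scores of the 6 mRNA libraries on the first and second principal components, which hold 70.2% and 9.68% of the variance; numbers beside points are replicate numbers.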

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

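The family sums, merging, total-count scaling and TMM without the most abundant sequence were chosen after the data were seen. For mRNA, 8 of 15 alternatives gave a count within 1.5 times of 5901, among them DESeq2 (6912) and quantile normalization (5628). A fold change of at least 1 left 2357 genes (1524 higher, 833 lower) and an adjusted p under 0.01 left 1216 (584 higher, 632 lower), both by stricter limits. Leaving out single libraries gave 1317 to 6823 genes, with 634 to 3658 higher and 683 to 3165 lower; the lowest came without early-flowering replicate 2 and the highest without late-flowering replicate 1, and the cause was not tested. For miRNA sequences, 11 of 18 alternatives stayed within 1.5 times of 28. An adjusted p under 0.01 left 8 (4 higher, 4 lower), no filter gave 20 higher among 40, and merging gave 6 higher among 19; leaving out single libraries gave 2 to 54, with 0 to 22 higher and 2 to 32 lower, of which 54 came without early-flowering replicate 1 and 2 without late-flowering replicate 3, and the cause was not tested. For families, the same step gave 4 to 19 calls, with 3 to 10 higher and 1 to 9 lower, and 19 came without early-flowering replicate 1. miR156/miR157 (−1.64 to −1.37), miR172 (1.07 to 1.28), miR319 (1.02 to 1.37) and miR2950 (1.83 to 2.06) passed in all 13 family alternatives. Families that did not pass changed sign: miR166 (−0.18 to 0.02 over the left-out libraries) was 0.01039 with TMM of the family sums, 0.006363 without early-flowering replicate 2 and 0.02328 without early-flowering replicate 3, miR396 (−0.21 to 0.04) was 0.009088 without early-flowering replicate 3 and 0.03756 without late-flowering replicate 2, and miR398 (−0.53 to 0.66) was −0.53 without early-flowering replicate 1; the cause was not tested. TMM without the most abundant sequence moved the median family log2 fold change from −0.00726 to −0.135. The replicate block gave 1502 genes (714 higher, 788 lower), 17 sequences (7 higher, 10 lower) and 4 families (1 lower). Libraries with the same number did not deviate together, with correlations across genes of −0.28, −0.016 and −0.24 for mRNA and −0.098, −0.076 and −0.34 for miRNA, and none correlated best with its own number. Gene lists and predicted targets were not run, since no gene names or transcripts were used here, and pseudocount alternatives do not apply to counts. In 1 simulated draw at the counts and spread of these miRNA libraries, 6.67% of 15 changes of log2 1 were recovered for sequences. Changes of that size or smaller may thus mostly have been missed, and depth and spread were not tested apart.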

Other observations

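Forms of miR398, a copper-responsive miRNA that targets superoxide dismutases, had fold changes of opposite sign over all libraries; this was picked out by inspection, and its test was chosen after the values were seen. The most abundant sequence with each core, jre-MIR398-5 (TGTGTTCTCAGGTCACCCCTT) and jre-MIR398_2-1 (TGTGTTCTCAGGTCGCCCCTG), differ by A15G and T21G, counted from the 5′ end. All 6 tested sequences with the first core had positive and all 5 with the second had negative fold changes, and none passed the edgeR test. Merging near-identical sequences left jre-MIR398_2-1 alone for the second core, still with a negative fold change. For the first core it left jre-MIR398-5, jre-MIR398_2-3 and jre-MIR398-8, all with positive fold changes, and none of the merged sequences passed. The 6 and 5 signs therefore count near-identical reads more than once and are not separate molecules. The higher level of the first form rested on early-flowering replicate 1, since its summed level was 2.03 times the late-flowering mean with that library and 1.12 times without it. Without that library, 4 of the 6 had positive fold changes, jre-MIR398-5 turned from 0.75 to −0.28, and 3 of the 11 sequences passed, while the second form was at 0.232 times the late-flowering mean, against 0.395 times with all libraries. Without early-flowering replicate 2, 4 of the 5 second-core sequences had negative fold changes. Inside a library, the ratio of first to second form was 5.72, 8.50 and 3.17 in early-flowering buds and 0.899, 1.73 and 0.886 in late-flowering buds, a difference of 2.27 in log2 ratio (exact two-sided permutation p = 0.1, the smallest possible). That difference was 1.94 to 2.65 when single libraries were left out. A scan of another measure, the ratio of the most abundant sequence to the next one not nested in it, covered 25 families. There the log2 difference was 1.97 for miR398 and −1.89 for miR169. The miR169 pair includes jre-MIR169_2-1, matched to a 3p arm, with counts of 12, 16 and 34 in early-flowering and 10, 7 and 3 in late-flowering libraries. The ratio separated the types in 9 of 25 families, where 10% would do so by chance. Some pairs, such as that of miR482, set a 3p arm against a 5p arm, unlike the miR398 forms. All ratios come from the same libraries, so the families are not independent.

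Early-flowering replicate 1 stood apart from the other miRNA libraries on the second principal component, with a score of 10.7. There miR398 reached 46600 CPM, against 16100 and 11500 CPM in the other early-flowering libraries and 16400 to 26200 CPM in the late-flowering ones. miR9560 reached 2880 CPM, against 685 and 509 CPM and 329 to 666 CPM. miR408, at 1820 CPM, was above the other early-flowering libraries (587 and 758 CPM) and near the late-flowering ones (1260 to 1630 CPM). The same held for miR397 (234 CPM against 91.6 and 130 CPM, with 213 to 313 CPM in late-flowering buds), miR530 (32700 CPM against 14100 and 15700 CPM, with 19500 to 33200 CPM) and miR403 (31700 CPM against 17100 and 20900 CPM, with 29100 to 33300 CPM). miR395, known from sulphate supply, was at 22300 CPM in early-flowering replicate 2, against 3370 and 7380 CPM in the others of that type and 3290 to 5090 CPM in late-flowering buds. These families were chosen after their values were seen.

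In the weighing that follows, the tests of the miR172 to miR156/miR157 ratio and of gene length and abundance were chosen after the result was seen. The patterns themselves were found in the data before any of their tests was written.

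miR156/miR157 was lower and miR172 higher in early-flowering buds. A common shift from scaling or an abundant sequence would leave their ratio inside each library alike, yet its log2 value differed by 2.68 without overlap; this value restates the sum of both fold changes and does not show that each family moved. After near-identical reads were merged, 8 of 13 miR156/miR157 sequences passed the edgeR test, 7 of them also called before merging and 1, jre-MIR156-64, called only after it. Merging did not join all near-identical forms, since among the 8, jre-MIR156-55 is jre-MIR156-30 with 1 added end base. Sequences of both arms are also among them and may share a precursor, so the 8 are not 8 separate molecules. Unlike sequences such as jre-MIR156-5 and jre-MIR156-59 each passed, so reads of 1 sequence do not account for all calls. For miR172, merging left 1 of 3 calls, so its sequence count does rest on near-identical reads. Walnut type and bud stage, which the labels tie together, stay open and untested.

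Differences between mRNA libraries of one type lay along the difference between types. Across genes, which are not independent, late-flowering replicate 1 minus replicate 3 correlated at 0.543 with the difference between types taken from the other libraries, and early-flowering replicate 1 minus replicate 2 at −0.408; for early-flowering replicates 2 and 3 the value was 0.0044. Thinning all libraries to the smallest total left the largest correlation at 0.537, but the totals of that pair differed by only 1.07 times, so thinning had little to correct and does not decide on depth. Removing trends over length and abundance left 0.547, and those trends held 0.433% of the variance of that library difference, which argues against them as its cause. Buds may have been collected at unequal stages within a type, a hypothesis that was not tested.

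Changed genes with consecutive IDs shared a direction in 857 of the 1406 consecutive pairs in which both changed, and went opposite ways in 549; over 200 shuffles of all 16797 pairs the means were 617 and 618, with at most 689 sharing a direction. Reads shared by near-identical copies would fade for unlike lengths. The ratio to shuffles was 1.35 for lengths over 1.5 times apart against 1.45 for closer lengths, so the excess was not confined to like lengths. The shuffles moved calls and directions together, so these ratios also count the clustering of changed genes. Among pairs in which both changed, 61.4% shared a direction for the unlike lengths and 60.2% for the closer ones. Reads running over from an abundant gene would fade for similar levels, but the ratio was 1.62 for levels within 2 times of each other and 1.29 for others. There, 66% and 58.7% of pairs in which both changed shared a direction. The shuffles did not keep pairs alike in level, and direction varied with abundance, which may raise the ratio of 1.62. Length only stands in for likeness, since no sequences were used here, so copies of unlike length that share reads are not excluded. Shared regulation or a variant region that differs between the types may contribute, and neither was tested.

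With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split, the 1 split with so high a count in each case, gave 5901 genes, 28 sequences and 5 families, and the highest other gave 0 for each. Every other split puts libraries of both types in each group, so the difference between types widens the spread within groups and lowers the count. Those 0 counts are therefore no measure of what chance alone would give.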
